A study of Caenorhabditis elegans with 2 samples.

How the data were processed

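The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of whole Caenorhabditis elegans. Per the labels, the worms were hermaphrodite young adults of strain OP485, collected 57.25 hours after synchronization as starved larvae. They carried LIN-40 with a GFP-FLAG tag at its C terminus, chromatin was sheared by sonication, and the tagged protein was pulled down with an antibody against GFP. The labels number the 2 samples biological replicates 3 and 4, and both fall into 1 group. No comparison between groups was possible, and libraries of a control were not analysed here.

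The authors' peak lists were the starting point, each deposited once on genome build ce10 and once on ce11. Per the labels and the deposited file listings, 1 list per build was called on each sample alone, 1 on both samples pooled, and all of these used a control alignment. A further list per build holds the regions that, per the labels, passed an irreproducible discovery rate (IDR) threshold; in both builds these were the regions of highest signal in the pooled list. The caller, the aligner and the IDR threshold are not given in the sources used here. Each deposited region has a signal value, set by the authors' caller, whose scale and normalization are not given in the sources used here. It was used to rank, filter and describe regions within a list. Each region also has a −log10 q-value, deposited by the authors, and a summit position. The −log10 q-value was at its maximum of 4.13 in all 3066 regions of the ce11 IDR list, so it ranked nothing there. The per-sample and pooled lists hold 30000 regions each and include background regions by design. Read depth is unknown, because the lists give no read counts.

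Positions were compared with the WBcel235 sequence and Ensembl release 115 annotation, the same assembly as ce11; the ends of the regions of every chromosome in the pooled ce11 list lay within the reference lengths. Lists on ce10 were used for counts, replicate overlap, the correlation between replicates and densities, with the end of each chromosome's last pooled region as its length, and no coordinate was converted between builds. A region was placed by its summit. The promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated transcript start. Each summit was put in the top class it met, in the order promoter window of a protein-coding gene, 5′ UTR, coding sequence, 3′ UTR, intron, non-coding RNA gene, pseudogene and intergenic.

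Replicate agreement was the share of the 3066 regions of highest signal in replicate 3 that overlapped by at least 1 bp such a region of replicate 4, with 1000 circular rotations as the chance level. The signal of the strongest overlapping region in each replicate gave the correlation across IDR peaks; peaks are not independent replicates. Densities were compared by a two-sided permutation test of 500 kb blocks with 100000 resamples, between X and autosomes, or between arms and centres (the middle 50% of each chromosome) within each autosome. Intervals of these ratios came from 2000 bootstrap resamples of blocks. Promoter shares were tested against 10000 circular rotations of the summits along each chromosome, two-sided. Signal at promoter and other summits was compared by a two-sided permutation test with 100000 resamples. The smallest p these tests can give is 1e-05 for permutations and 0.0002 for rotations.

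For 31 gene lists, having a summit in the promoter window was tested with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over the lists. Lists of protein-coding genes were set against the other protein-coding genes, and lists of non-coding RNA genes against all other genes. The names daf-21 (present as hsp-90), rad-54 and ram-4 had no match in the annotation. For 10 motifs, windows of 100 bp either side of a summit were paired with windows 1500 bp downstream that met no IDR peak. They were compared by an exact sign test with the same adjustment over the motifs. For flanks, downstream means toward higher coordinates on the chromosome, whatever the strand of the nearest gene. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. P-values over genes, peaks or blocks describe the pooled list and not the spread between animals.

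The lists, the motifs, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the genes nearest to the 15 strongest promoter summits, every member of the NuRD and MEC list, the 4 members with the strongest summits of each enriched list (2 for a depleted one), and the 5 strongest summits outside promoter windows. The alternatives were a stricter threshold (the stronger 50% of IDR peaks), the strongest regions of the pooled list, each replicate's own list in place of the pooled one, thinning of summits within 500 bp, other promoter windows and starts, other block sizes and denominators, other overlaps, other flanks and backgrounds, and ce10.

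The tests were run on simulated data. For the gene list test, 20 of 20 lists simulated at an odds ratio of 5 were called among 19973 genes, with a median estimate of 4.38. Of 80 lists without an effect, 0 were called. Each simulated list had 60 genes, as many as the chaperone list, and the genes were drawn independently. Shorter lists, such as the 10 NuRD and MEC genes, were not simulated. The result therefore does not show that such an effect would be found in them. For the X comparison, a simulated ratio of 2 came out at 2.00 over 3066 summits. The number of summits per chromosome was set from that ratio, so this checks the computation alone. Positions were drawn evenly along each chromosome, so the permutation test was not tried on clustered peaks. For promoter shares, 2 of 40 random sets were called. For motifs, planting 1 motif at 20% of 3066 summits gave 1 call, and no planting gave 0 calls. These summits lay at random positions, without the higher G and C content of the real ones. The 0 calls therefore do not show how the flank comparison behaves under that difference. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.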

Results

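LIN-40 is an MTA-type subunit of the nucleosome remodelling and deacetylase complex (NuRD), which couples a chromatin remodelling ATPase with a histone deacetylase. The series maps where the tagged protein was recovered on the chromatin of whole young adult worms, in 2 biological replicates of 1 group. The IDR list on ce11 held 3066 peaks in 2901 distinct intervals, with a median width of 395.5 bp (range 116 to 4540). Signal values ran from 99.97 to 2816, with a median of 164. The IDR list on ce10 held 4635 peaks, although 3066 regions of the pooled ce10 list reached the lowest signal of the ce11 list. In each build the IDR peaks were the regions of highest signal in the pooled list, so the builds differ in where the threshold fell. Positions below are on ce11, and distances to a gene's start are negative where the summit is upstream.

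The replicates recovered largely the same places. Of the 3066 strongest regions of replicate 3, 2465 (80.4%, exact 95% interval 78.9 to 81.8) overlapped one of the 3066 strongest of replicate 4. Circular rotation gave 2.36% on average and 3.78% at most. Across the 3045 IDR peaks with a region in both full lists, signal had a Spearman rho of 0.83 and a Pearson r of 0.89 on the log2 scale. The IDR peaks were the regions of highest signal in the pool of these same replicates. The correlation across them is therefore not an independent measure of agreement. Replicate 4 had a median signal 1.15 times that of replicate 3, with an SD of 0.39 on the log2 scale across peaks.

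**Figure D1:**
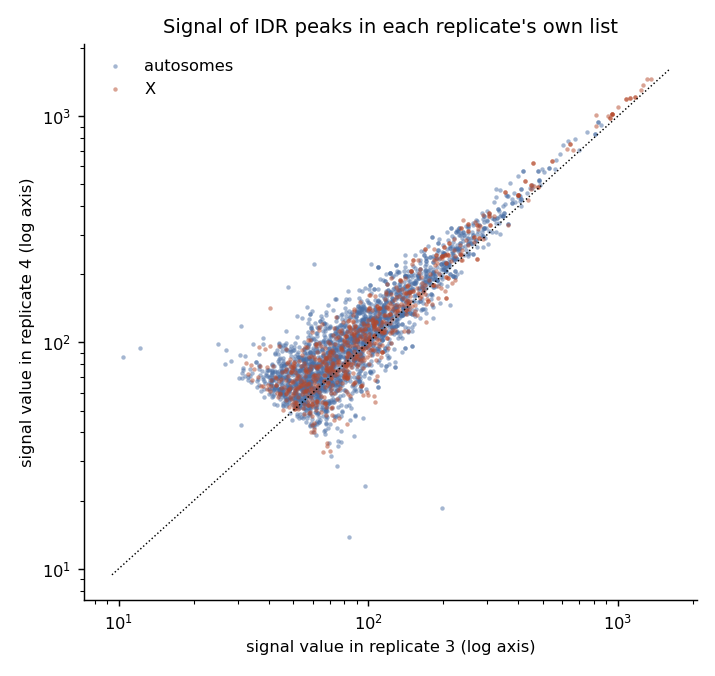
Each point is an IDR peak with a region in both full lists (3045), placed by the authors' signal value in replicate 3 (x axis, log scale) and in replicate 4 (y axis, log scale), with X in red, autosomes in blue and the line of equality dotted. The points lie along the line and mostly above it (rho 0.83), and the points of highest signal are from X.

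The chromosomes were occupied unevenly. X held 715 peaks, or 40.4 per Mb, against 28.5 per Mb on the autosomes, a ratio of 1.42 (bootstrap 95% interval 1.24 to 1.61; permutation p = 0.00025). Among autosomes the density ran from 20.5 per Mb on V to 38.5 per Mb on III, with 31.8 on I, 28.5 on II and 27.3 on IV. The bootstrap interval and permutation p of the X ratio took blocks as their units. They leave out this spread between chromosomes, and X is 1 chromosome. The 3066 strongest regions of replicates 3 and 4 placed 715 and 714 on X. Autosome arms held 22 peaks per Mb against 35.0 in the centres, a ratio of 0.628 (0.538 to 0.725; permutation p = 1e-05, the smallest the test can give). On X the arms held 41.5 and the centre 39.2 per Mb, and the permutation test found no difference between them (p = 0.615); whether X and the autosomes differ in this respect was not tested. Per protein-coding gene the ratio of X to autosomes was 1.92, since X is poorer in genes.

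**Figure D2:**
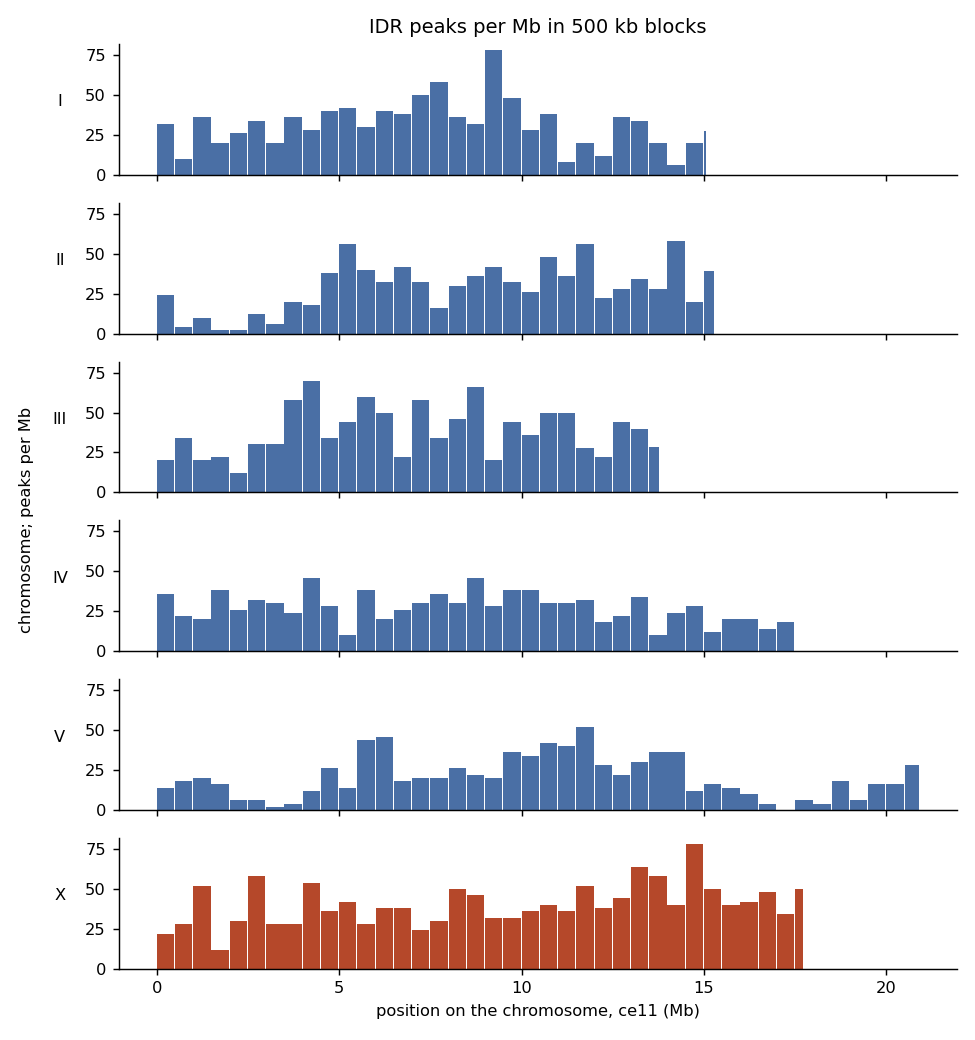
Bars give IDR peaks per Mb in 500 kb blocks along each chromosome (x axis, position on ce11 in Mb), autosomes in blue and X in red. Peaks are denser in the centres than the arms of the autosomes (35.0 against 22 per Mb), and X averages 40.4 per Mb.

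The 13 peaks of highest signal in the list all lay on X; the autosomal peak of highest signal, at the ribosomal protein gene rpl-3, ranked 14. This count and the next 2 comparisons were chosen after the values were seen. Of the 50 strongest peaks 24 were on X, and of the 100 strongest 34. The median signal on X was 170 against 163 on autosomes, a difference of 0.06 on the log2 scale that a permutation test did not separate from 0 (p = 0.2). The 5 strongest summits outside promoter windows were all on X. The strongest peak of all, X 6296027 to 6297085, had a signal of 2816 (1353 in replicate 3 and 1456 in replicate 4) and its summit lay in an intron, at -3375 bp from the nearest start, that of cest-16. The peak at X 11093620 to 11094695 (2772; 1311 and 1466) was intergenic, 3979 bp from the start of W02H3.3. The peak at X 9465348 to 9466375 (2633; 1257 and 1373) was intergenic, 2522 bp from ZK899.6, and that at X 13700376 to 13701287 (2536; 1234 and 1312) was intergenic, -6032 bp from K02D3.1. The last, X 8035877 to 8037067 (2304, with 1121 and 1198), was intergenic, -4860 bp from xol-1, a switch gene of sex determination and dosage compensation. Its summit lay within 300 bp of the tRNA gene C18A11.t2.

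Summits lay in promoter windows more often than after rotation, and the share depended on the window and starts chosen. Of the 3066 summits, 1675 (54.6%, exact 95% interval 52.8 to 56.4) fell in the promoter window of a protein-coding gene, against 25.6% ± 0.86 (SD over rotations) by rotation (p = 0.0002, the smallest the test can give). The median summit lay 611 bp from the nearest start, 73.2% of summits lay upstream of it, and promoter summits had a median position of -209 bp. Coding sequence held 2.12% of summits against 18.7% by rotation, introns 14.5% against 27.6%, 3′ UTRs 1.08% against 2.42% and pseudogenes 0.163% against 2.42% (permutation by rotation, adjusted p = 0.00027 for each, the smallest here). By the same permutation, non-coding RNA genes held 2.84% against 0.811% (adjusted p = 0.00027), intergenic sequence 24.3% against 22% (adjusted p = 0.0096), and 5′ UTRs 0.359% against 0.418% (adjusted p = 0.755). Peaks in promoter windows had a median signal of 172, against 155 for the 1391 other peaks, a difference of 0.15 on the log2 scale (permutation p = 3e-05); among the stronger 50% of the peaks it was 0.08.

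The 15 strongest promoter summits included 3 at X-linked genes and several at genes of the ribosome; no test was made of what these 15 have in common. The strongest lay at -724 bp from nspc-17 on X (signal 2367). It was followed by rpl-3, a protein of the large ribosomal subunit (III 3867056 to 3867869, signal 1765; 854 in replicate 3 and 914 in replicate 4), with its summit at -296 bp. The next summits were nearest, among protein-coding starts, to those of ZK1248.17 (1747, at 696 bp) and egg-5 (1633), a gene of egg activation. The first lay past the end of ZK1248.17 and outside its window, and counted as a promoter summit through the window of another gene. They lay closer to genes for SL2 spliced leader RNAs, at -20 bp from sls-2.1 and -22 bp from sls-2.4. They were followed by tasp-1 (1591, at -58 bp), Y17G9B.5 (1462, a peak shared with rpl-20), cdc-48.1 (1398), a AAA ATPase that unfolds ubiquitinated proteins, fbxb-58 (1388) and ins-39 (1368) on X, rpl-15 (1348), drr-2 (1264), cox-5A (1208), a subunit of cytochrome c oxidase, rpl-35 (1143), tag-340 (1078) and the HSP70-family chaperone hsp-1 (1075).

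Of the lists of protein-coding genes, the cytoplasmic ribosomal proteins had a summit most often. A summit lay in the window of 1979 of 19973 protein-coding genes (9.91%). Of the cytoplasmic ribosomal protein genes 56 of 78 (71.8%) had one, an odds ratio of 23.8 (Fisher's exact test, adjusted p = 3.6e-38), and of 7.74 when each summit was given to the nearest start alone. The strongest were rpl-3 (1765), rpl-20 (1462), rpl-15 (1348) and rpl-35 (1143), and at 56 of the 56 genes the summit, from 54 peaks in all, lay upstream of the start, at a median of -298 bp. Translation factors had a summit at 18 of 41 genes (43.9%, odds ratio 7.17, exact test, adjusted p = 5.9e-08), led by ifet-1 (949), the translation initiation factor 5A gene iff-2 (840), eif-3.C (555) and the elongation factor gene eef-2 (554). Genes of the mitochondrial respiratory chain had a summit at 19 of 42 (45.2%, odds ratio 7.57, exact test, adjusted p = 1.4e-08), led by cox-5A (1208), the ATP synthase gene atp-1 (541), cox-5B (533) and cox-6B (441). The chaperone list had 24 of 60 (40%, odds ratio 6.12, exact test, adjusted p = 3.2e-09), with hsp-1 (1075), hsp-60 (1001), cct-8 (882) and hsp-90 (879). Proteasome subunits had 11 of 33 (33.3%, odds ratio 4.57, exact test, adjusted p = 0.00056), with rpn-3 (585), rpn-11 (359), pbs-1 (265) and rpn-2 (200.5). The chaperone gene hsp-110 had the identical signal (585) to rpn-3, so these 2 lists are not fully independent. The vacuolar ATPase, a proton pump, had 6 of 20 (30%, odds ratio 3.91, exact test, adjusted p = 0.022), with vha-12 (358), vha-8 (358), vha-13 (258) and vha-1 (248). The call for chaperones ended with the nearest start alone (odds ratio 2.44, exact test, adjusted p = 0.0507; from 2.5e-10 over the alternatives), and that for the proteasome with the stronger 50% of the peaks (odds ratio 2.90, adjusted p = 0.0778; from 0.00012).

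**Figure D3:**
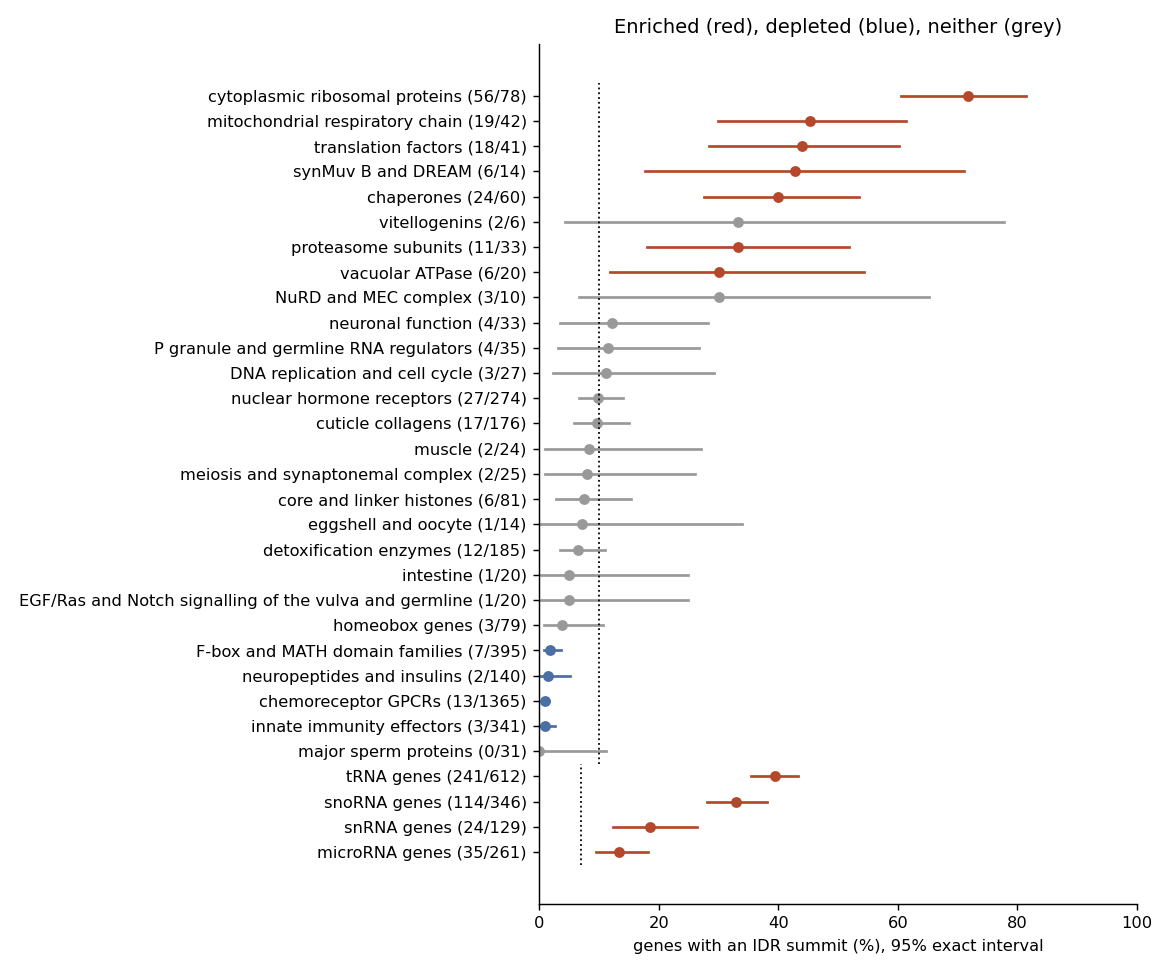
For each gene list, the point gives the percentage of its genes with an IDR summit in the promoter window and the line the exact 95% interval, with counts beside the name and the share of other genes dotted; red lists were enriched, blue ones depleted and grey ones neither, at an adjusted p under 0.05. Ribosomal protein genes stand highest at 71.8%, and chemoreceptor genes at 0.952%.

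Of the 2 lists of chromatin regulators, synMuv B and DREAM passed the test and NuRD and MEC did not. The synMuv B and DREAM list, repressors of cell cycle and germline genes, had a summit at 6 of 14 genes (42.9%, odds ratio 6.84, Fisher's exact test, adjusted p = 0.0031). They were led by lin-54 (IV 13240413 to 13240922, signal 944), lin-9 (583), the retinoblastoma-like gene lin-35 (363) and the E2F gene efl-1 (340). Of the NuRD and MEC genes 3 of 10 had one (odds ratio 3.90, exact test, adjusted p = 0.125): lin-53, the RbAp46/48 histone chaperone (I 9619788 to 9620206, signal 646; 300 in replicate 3 and 344 in replicate 4), dcp-66 (138; 47.3 and 92.3) and mep-1 (111; 44.9 and 70.1). No IDR summit lay in the windows of lin-40 itself, the Mi-2 ATPase genes let-418 and chd-3, the deacetylase gene hda-1, egl-27, rba-1 or mbd-2. From replicate 3's own list, and with the stronger 50% of the peaks, dcp-66 and mep-1 had none; from replicate 3's own list hda-1 had 1 and egl-27 had 2. Against rotated summits, in place of other genes, the list of 10 passed (permutation by rotation, adjusted p = 0.031; up to 0.642 over the other alternatives).

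The remaining 15 lists, on the germline, other tissues and regulators, passed the test in neither direction. A summit was found at 4 of 35 P granule and germline RNA regulators, 2 of 25 meiosis genes, 1 of 14 eggshell and oocyte genes, 0 of 31 major sperm protein genes and 2 of 6 vitellogenin genes. It was found at 17 of 176 cuticle collagens, 2 of 24 muscle genes, 1 of 20 intestinal genes, 4 of 33 neuronal genes and 27 of 274 nuclear hormone receptors. The counts were 3 of 79 for homeobox genes, 6 of 81 for histones, 3 of 27 for DNA replication and cell cycle, 1 of 20 for Ras and Notch signalling and 12 of 185 for detoxification enzymes. None of them passed (adjusted p from 0.125 to 1 by Fisher's exact test). With other settings the exact test called the homeobox genes (adjusted p = 0.039 with the window of 500 and 100 bp; up to 0.515 otherwise) and the detoxification enzymes (adjusted p = 0.00096 with the stronger 50% of peaks; up to 0.911) depleted. Against rotated summits cuticle collagens (2.77 times the expected count) and nuclear hormone receptors (2.78 times) became enriched. Rotation sets genes against random positions. Against other protein-coding genes (9.91%) both lists stood at a near-equal share, 9.66% for collagens and 9.85% for nuclear hormone receptors.

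Chemoreceptors, innate immunity effectors, F-box and MATH genes, and neuropeptides and insulins had a summit less often than other protein-coding genes. Chemoreceptor genes had a summit at 13 of 1365 (0.952% against 10.6% of other genes, odds ratio 0.081, Fisher's exact test, adjusted p = 1e-44), the strongest being sri-5 (420) and srh-16 (361). Innate immunity effectors had 3 of 341 (odds ratio 0.079, exact test, adjusted p = 3.6e-11), with clec-126 (499.8) and fipr-17 (148); the odds ratio was 0.052 from replicate 3's own list and 0.047 with the stronger 50% of the peaks. F-box and MATH genes had 7 of 395 (odds ratio 0.161, exact test, adjusted p = 6.4e-10), with fbxb-58 (1388) and fbxb-85 (579), and odds ratios from 0.089 to 0.256 over the alternatives with Fisher's test. Neuropeptide and insulin genes had 2 of 140 (odds ratio 0.131, exact test, adjusted p = 0.00027), ins-39 (1368) and flp-23 (115); from replicate 4's own list flp-23 had none, and the odds ratio was 0.065. With the window of 2000 and 200 bp it was 0.30. Against rotated summits the calls for F-box and MATH genes (permutation by rotation, adjusted p = 0.228; from 4.9e-14 over the alternatives) and for neuropeptides and insulins (adjusted p = 0.291; from 3.8e-05) ended.

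Small RNA genes, several kinds of which are transcribed by RNA polymerase III or as short independent units, carried many summits. Of 612 tRNA genes 241 (39.4%, exact 95% interval 35.5 to 43.4) had one, against 6.67% of all other genes (odds ratio 9.09, Fisher's exact test, adjusted p = 4.3e-114). The median summit lay at -9 bp from the tRNA start, and 83.4% of the 241 lay within 150 bp of it. The highest were R04A9.t1 (864), C18A11.t1 and C18A11.t2 (803 for a shared summit) and M02F4.t1 (638), all on X. The summit of C18A11.t1 and C18A11.t2 lies in the same interval as the stronger summit upstream of xol-1. A summit was found at 46.7% of the 276 tRNA genes of X and 33.3% of the 336 on autosomes (Fisher's exact test, p = 0.00087, chosen after the values were seen). The snoRNA genes had 114 of 346 (32.9%, odds ratio 6.63, exact test, adjusted p = 1e-44), and the snRNA genes 24 of 129 (18.6%, odds ratio 3.01, adjusted p = 3.8e-05). For 60 of those 114 snoRNA genes the summit also lay in a protein-coding window. Among the 4 strongest, C06A1.9 shared its peak with cdc-48.1, and K11H12.12 and K11H12.13 with rpl-15, while the summit of T27A8.8 (1703) lay at -804 bp. The strongest of the snRNA list were the SL2 genes sls-2.1 (1747), sls-2.4 (1633) and sls-2.2 (1055), with summits at -20, -22 and -24 bp, and R07E5.16 (789.8, at -21 bp). MicroRNA genes had 35 of 261 (13.4% against 7.06% of all other genes, odds ratio 2.04, exact test, adjusted p = 0.00088). The microRNA genes with a summit included the clustered mir-54, mir-55 and mir-56, which share 1 peak on X (651), and mir-354 (577). Over protein-coding genes alone the share was higher, at 9.91%. Odds ratios of the non-coding lists are therefore not on the same scale as those of the protein-coding lists. The microRNA call ended with the nearest start alone (odds ratio 1.30, exact test, adjusted p = 0.515; from 1.5e-06 over the alternatives).

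The sequence at summits was richer in G and C (43%) than the flanks (36.5%) or the genome (35.4%), and several motifs were concentrated there. Over 2829 pairs, GAGAGA was present at 41.3% of summits and 11.8% of flanks (exact sign test, adjusted p = 2.8e-140). CTGCGTCT, a core promoter motif of broadly expressed genes, was at 13.6% against 1.17% (exact test, adjusted p = 7.2e-78), and the E-box CACGTG at 9.86% against 3.85% (adjusted p = 2.7e-19). The SP1-like CNCCGCCC was at 4.03% against 0.954% (exact test, adjusted p = 1.6e-13), and the E2F-like TTTSSCGC at 5.73% against 3.36% (adjusted p = 2.8e-05). The homeodomain site TAATTA (4.70% against 9.12%, exact test, adjusted p = 2.9e-10), the heat shock pair TTCNNGAA (8.27% against 13.2%, adjusted p = 1.8e-09) and CCAAT (29.8% against 35.1%, adjusted p = 2.8e-05) were rarer at summits. The GATA site TGATAA (17.6% against 17.4%, exact test, adjusted p = 0.805) and the nuclear receptor site AGGTCA (5.76% against 4.98%, adjusted p = 0.243) passed in neither direction. Against GC-matched promoters of genes without a summit, the first 3 motifs kept their direction with smaller differences for GAGAGA (39.7% against 24.2%) and CTGCGTCT (12.6% against 4.93%), TTTSSCGC and TTCNNGAA lost their calls (exact test, adjusted p = 0.764 and 0.25), and CNCCGCCC turned to rarer at summits (3.76% against 8.21%). That comparison included summits outside promoter windows (1391 of the 3066 in the list), so it also set other sequence against promoters. In it AGGTCA was rarer at summits (5.93% against 8.87%) and TGATAA more frequent (19.8% against 15.9%). With the stronger 50% of the peaks, against flanks, TGATAA was rarer (12.3% at summits). TAATTA lost its call at promoter summits alone (exact test, adjusted p = 0.152).

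**Figure D4:**
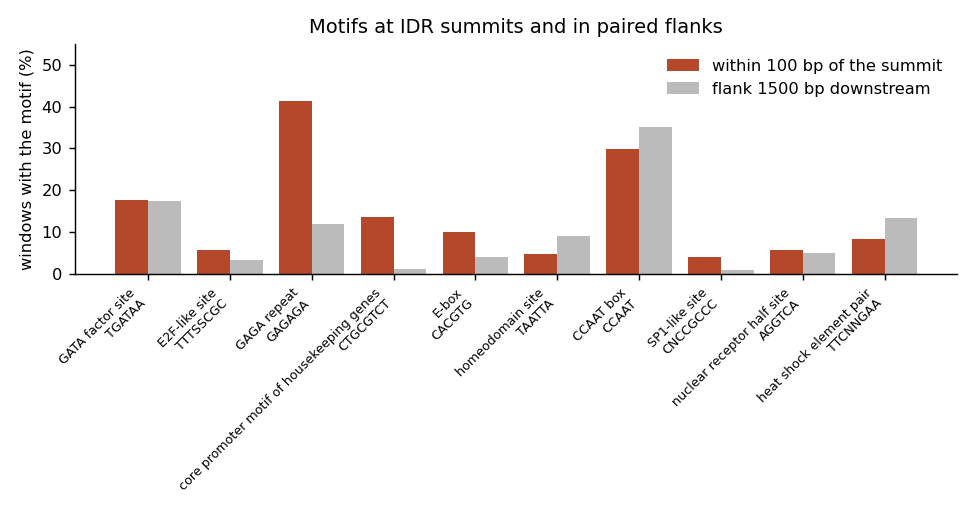
Bars give the percentage of windows that hold each motif on either strand, within 100 bp of IDR summits (red) and in the paired flank 1500 bp downstream (grey), over 2829 pairs. GAGAGA stands at 41.3% against 11.8%, and TAATTA at 4.70% against 9.12%.

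The lin-40 locus, whose sequence the tagged construct also carries, had no surplus of called regions. In the 47.8 kb around lin-40 (V 3704988 to 3712796, with 20 kb on either side), replicate 3 had 14 regions in its full list and replicate 4 had 10, against a median of 12 in windows of that size. At least as many regions were found in 46.8% of windows for replicate 3 and 59.0% for replicate 4. With 50 kb on either side replicate 3 had 17 regions against a median of 32, and 75.7% of windows had at least as many. Replicate 4 had 14 against 31 there. The 2 IDR peaks there lay in an intron 1275 bp inside unc-132 (signal 123) and at -523 bp from nrsn-1 (112).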

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

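Most tests of explanations were fixed before their result was seen; those of a background shift on X and of high transcription were chosen after it. No biological difference between groups was tested, because the samples form 1 group.

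Outside the IDR list, 3750 further regions of the pooled ce11 list had the highest −log10 q-value of that list (4.13), the value that every IDR peak has. This result was picked out because it is a signal in regions that the comparisons above did not use.

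The higher density of peaks on X was weighed against tRNA genes, GAGA repeats and background. Without peaks within 300 bp of a tRNA gene the ratio of X to autosomes was 1.25 (permutation p = 0.017), down from 1.42, so tRNA genes may account for part of the excess but the rest remained. Among peaks without GAGAGA the ratio was 1.56 (permutation p = 1e-05, the smallest it can give), which argues against the repeat. The weakest 50% of the pooled list had a ratio of 1.16 (permutation p = 0.054), below the bootstrap interval of the IDR peaks (1.24 to 1.61), which argues against a shift of background as the whole cause. What stays open is any property of X chromatin, or of anti-GFP pull-downs in general, that a library of another bait would be needed to test.

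The frequent summits at tRNA genes were weighed against reads shared between identical copies and against neighbouring promoters. Of the 140 tRNA genes whose sequence occurs once in the genome, 26.4% (exact 95% interval 19.3 to 34.5) had a summit, and of the 472 with further copies 43.2%. The share at sequences that occur once lay above the 6.67% of other genes. This argues against reads shared between identical full-length copies as the whole cause, though they may add to the share of the copied genes. A sequence was taken to occur once if its full length had no other exact match. Near-identical genes can still share shorter reads, which was not tested. Of the 239 tRNA genes over 2000 bp from every protein-coding start, 37.7% (31.5 to 44.1) had a summit, which argues against neighbouring promoters. Recovery of open, highly transcribed chromatin in any pull-down stays open, untested.

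The summits at ribosomal protein genes were weighed against signal along transcribed bodies and against high transcription as such. Of the 54 summits between 1000 bp upstream and the end of these genes, 100% lay upstream of the start or within 100 bp inside it (exact 95% interval 93.4 to 100), which argues against signal along gene bodies. Of the vitellogenin and major sperm protein genes, chosen as families of high transcription, 5.41% (2 of 37) had a summit. That is fewer than of the ribosomal protein genes (Fisher's exact test, p = 3.3e-12). The major sperm protein genes had 0 of 31 and the vitellogenin genes 2 of 6 (33.3%). Transcription was not measured, and whether major sperm protein genes were highly transcribed in worms of this stage is not known from these lists. Because these families are transcribed in 1 tissue each and the worms were used whole, a general effect of transcription and a preference of LIN-40 cannot be told apart.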

How the results depend on the processing

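Of 85 alternative values for the main results, 73 kept their direction and their side of the threshold, or stayed within their range (lists and motifs by their count alone, whichever were called), and 12 moved; all were chosen before the data were examined. The X to autosome ratio ran from 1.36 to 1.92, the arm to centre ratio from 0.607 to 0.785, the promoter share from 43.2% to 67.7% and the log2 difference in signal at promoters from 0.08 to 0.19, each past its threshold under every alternative run. With either replicate's own list the same 11 lists were enriched and the same 4 depleted. The strongest regions of the pooled list were identical to the IDR list, so that alternative could move nothing. Its values are counted among the 73 and add no support. The IDR peak count cannot leave out a replicate, since the deposited list was derived from both.

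The values that moved are given here, together with calls of lists, motifs and genes that changed while their count stayed in range. The ce10 IDR list held 4635 peaks. Replicate overlap was 67.5% with a reciprocal overlap of 50%, 74.0% with summits within 100 bp, 83.3% for the stronger 50% of regions, 77.3% for 2 times as many and 78.9% on ce10. The Spearman correlation of signal between the replicates was 0.79 with summits within 100 bp. Against GC-matched promoters 3 of 5 enriched and 2 of 3 depleted motifs kept their call and 2 others gained one. Nearest starts alone kept 9 of 11 enriched lists. The counts under these 2 alternatives stayed within their range and are not among the values that moved. With rotated summits 14 lists were enriched, 3 of them new, 2 were depleted in place of 4, and the ratios for cuticle collagens (2.77) and nuclear hormone receptors (2.78) turned to enriched, since rotation compares genes with random positions and not with other genes. At the lin-40 locus at least as many regions were found in 75.7% and 79.6% of windows for replicates 3 and 4 with 50 kb, and in 37.3% with IDR peaks. TGATAA turned to rarer at summits with the stronger 50% of peaks (12.3%); against GC-matched promoters CNCCGCCC (3.76%) and AGGTCA (5.93%) turned to rarer. For the overlap, correlation, locus and motif values the cause was not tested. Of 70 named genes, 15 lost their summit with the window of 500 and 100 bp, 4 with the stronger peaks, 2 with 1 start per gene (cox-6B and hsp-90) and 1 without replicate 3; without replicate 4, 4 changed, and rba-1 gained 1 with the window of 2000 and 200 bp. Read depth is unknown and limits what the lists can show. No paired analysis was possible because the series has 1 group.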

Other observations

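The tests of gene families and of the strongest X peaks were chosen after the peaks were seen, though what the X tests should show was written before their results.

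Beyond the fixed lists, 186 families of protein-coding genes with at least 8 members, grouped by symbol, were scanned with Fisher's exact test. Of these, 4 were enriched and 0 depleted after adjustment over the families. The rsp genes, which encode SR splicing factors, had a summit at 7 of 8 (exact test, adjusted p = 0.00013), with rsp-1 and rsp-2 sharing a signal of 361. The vps genes of vesicle sorting had 12 of 31 (exact test, adjusted p = 0.0019), led by vps-32.1 (532) and vps-4 (436). The signal at vps-51 (363) was the same as that at lin-35 of the synMuv B list. The mitochondrial ribosomal protein genes named mrpl had 12 of 41 (exact test, adjusted p = 0.021), led by mrpl-28 (458). Those named mrps had 5 of 29 and did not pass (exact test, adjusted p = 0.701). The lin genes, named for cell lineage defects and not for 1 function, had 14 of 47 (exact test, adjusted p = 0.0076), several of them members of the synMuv B list.

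The strongest peaks on X may coincide with recruitment sites of the dosage compensation complex, a condensin-containing complex that binds X in hermaphrodites at sites with a motif around GCGCAGGG. Of the 13 X peaks stronger than every autosomal peak, 9 (69.2%) held GCGCAGGG within 100 bp of the summit, more often than the other IDR peaks (Fisher's exact test, p = 3.2e-18). The motif was present at 8 of the 702 other X peaks, 4 of 2351 autosomal peaks and 3 of 3066 downstream flanks. Of the 31-mers sampled around those 13 summits, 0% of 234 occurred more than once in the reference, which argues against a pile-up of reads on multicopy sequence. These peaks are a small part of X: without every peak that holds the motif the density ratio of X to autosomes was still 1.39 (permutation p = 0.00048). Whether LIN-40 sits at such sites, or whether they are recovered in any anti-GFP pull-down, cannot be settled from these lists, and the sites were not compared with a map of the complex.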
